A study of Homo sapiens with 2 samples.

How the data were processed

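Polyadenylated RNA of HepG2 cells, a human liver cancer line that keeps many hepatocyte functions, was sequenced after transfection of a negative control siRNA or of an siRNA against SPRTN. Per the labels' protocols, RNA was enriched with oligo(dT) beads, fragmented, and copied to cDNA from random hexamers. Each group has 1 library, so 1 control library was set against 1 SPRTN siRNA library. The title of the FPKM table speaks of row means, and what was averaged is not given in the sources used here. The values fit whole reads of a single library or of pooled reads, so a column may stand for more than 1 culture. Groups were taken from the treatment label of each sample. The columns of the deposited tables carry short names, and the column with the siRNA prefix was assigned to the SPRTN siRNA library and the other to the control.

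The authors deposited a table of FPKM values (fragments or reads per kilobase of gene, scaled by library depth) for 60448 genes. Per the submitters' processing notes, the genome build was GRCh38.p13 and edgeR was used, with no version or role stated. The aligner, the counter, the gene annotation release, the use of strand and the trimming are not given in the sources used here. A second table of the authors holds length-scaled coverage per gene, a signal that equals the FPKM for the SPRTN siRNA library and 1.44 times the FPKM for the control, so it is not corrected for depth. That table also gives the authors' log2 fold change, which equals the log2 ratio of the deposited FPKM without a pseudocount. It gives the authors' p-value and adjusted p-value per gene, from a test of 1 library against 1 library whose method is not given in the sources used here. The deposited calls were compared with these columns, and every gene called by the authors had an absolute log2 fold change of at least 1 and an adjusted p below 0.005.

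Depth was recovered from the values. FPKM times the mean transcript length of the gene in GENCODE release 29 (GRCh38), which has a length for 94.1% of the genes, is a multiple of the worth of 1 read. Of values up to 20 reads, 93.3% in the SPRTN siRNA library and 94.0% in the control lay within 0.05 of a whole number. For genes with 1 annotated transcript these shares were 98.4% and 98.6%, and for genes with more they were 83.8% and 84.7%. The worth of 1 read gives about 67100000 assigned reads for the SPRTN siRNA library and 96400000 for the control. Ratios are given with exact Clopper-Pearson 95% intervals of the split of a gene's recovered reads between the libraries. These intervals cover counting error only, since PCR copies are not independent molecules and there is no replicate to show the spread between cultures. The interval's bounds lay a median of 0.09 from its centre on the log2 scale.

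All comparisons used the deposited FPKM as log2(FPKM + 1) in the SPRTN siRNA library minus log2(FPKM + 1) in the control, among 13203 genes with a mean FPKM of at least 1. A fold change on this scale understates the change of low genes, and folds printed beside FPKM values are plain ratios of FPKM. No test across libraries is possible with 1 library per group, so no p-value was computed and genes were counted by a size rule of 2-fold. The plan had foreseen counts with TMM scaling for the case that counts were given. The values are FPKM, so the FPKM version of the plan was used.

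Before the data were examined, 43 gene lists were fixed. The median log2 ratio of each list with at least 5 measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A median under percentile 2.5 or over percentile 97.5 is called lower or higher, as a description of these libraries. Members of a list are regulated together, which random lists are not, so the percentile does not measure how often another pair of cultures would give the same shift. In simulated data on the 13203 genes, lists of 25 genes with no shift were called in 4.5% of draws, those shifted by 0.2 in 49.0% and those shifted by 0.5 in 99.0%. The simulated noise was normal with the standard deviation of the real log2 ratios (0.39), and wider for genes of low expression. Its spread thus exceeded the real one, so the shares do not give how often real lists with such shifts would be called.

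The rule for the genes named in the text was also fixed before the data were examined. It takes SPRTN, the 12 protein-coding genes with the largest and the 12 with the smallest log2 ratio at a mean FPKM of at least 5, and members of the lists. From a called list it takes the 3 members farthest in the direction of the median and the 1 farthest the other way, and from another list up to 2 members with the largest absolute log2 ratio. Genes named outside this rule are marked as chosen after their values were seen, except ACTB, which was picked by hand from the authors' deposited table. Some genes that the rule takes are not reported here, but they remain in all counts and medians.

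For the siRNA, the guide strand was taken as the reverse complement of the sequence in the series' design text. 3' UTRs came from the protein-coding transcripts of GENCODE release 29 with an annotated stop codon, which cover 11134 (99.7%) of the 11172 protein-coding genes measured. A gene was counted as having a site if any of its 3' UTRs held it. The 8-base site pairs with guide positions 2 to 8 and has an A opposite position 1. The 7-base site leaves out that A. Other partial matches to the guide, such as TGGTTAA, were not counted as sites. Genes with the site were compared with 10000 random gene lists matched on mean expression and 3' UTR length. All 7-base words present in the longest 3' UTR of at least 50 genes were then ranked by a rank-sum score of the log2 ratio. Before that, linear trends on log 3' UTR length and log expression and a quadratic trend on GC content were removed from the ratio. In simulated data, a word whose genes were shifted by 0.1 ranked first in 5 of 5 draws, and by 0.2 in 5 of 5.

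The alternatives were scaling by the median of ratios, centring on the median gene, a pseudocount of 0.1, no filter beyond 1 read, a mean FPKM of at least 5, protein-coding genes alone and unmatched random lists. For the seed sites they were a 7-base site, matching on expression alone and the passenger strand. Alternatives chosen after seeing the data were the recovered reads, leaving out the mitochondrially encoded genes, genes without a seed site, repair lists without SPRTN and cell cycle members, and a 7-base passenger site. Scripts ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. Genes with near-identical copies, such as histones, the UGT1A and UGT2B families, AKR1B10 and genes with processed pseudogenes such as PPP1R2, may share reads with their copies, and their values are uncertain to that extent. UGT1A1 also overlaps the other UGT1A genes.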

Results

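The data are 2 RNA-seq libraries of HepG2 cells, a human hepatoblastoma-derived liver line. The cells were transfected for 24 h with 40 nM of a negative control siRNA or of an siRNA against SPRTN, and RNA was isolated at 72 h. SPRTN is the protease that degrades proteins crosslinked to DNA, and the comparison asks how its depletion changes gene expression. The control library had about 96400000 reads assigned to genes and the SPRTN siRNA library about 67100000. With 1 library per group, no difference reported here has a replicate check, and intervals cover counting error only.

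SPRTN itself was lower in the SPRTN siRNA library, as its label states. Its level was 7.81 FPKM in the control library and 2.07 FPKM in the SPRTN siRNA library, from 1349 and 249 reads. That is 26.5% of the control level (95% interval 23.1 to 30.4%), or 3.77-fold lower (3.29 to 4.33), and the log2(FPKM + 1) ratio was -1.52. SPRTN (ENSG00000010072) lies on chromosome 1 from 231337104 to 231355023 on the plus strand of GRCh38. The 19-base target GTCAGGAAGTTCTGGTTAA matches 231353422 to 231353440, inside exon 5, in the 3' UTR. Of the 6 annotated SPRTN transcripts, 1 holds the target, and the FPKM sums over all of them. No other gene's annotated transcript held a full match.

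**Figure D1:**
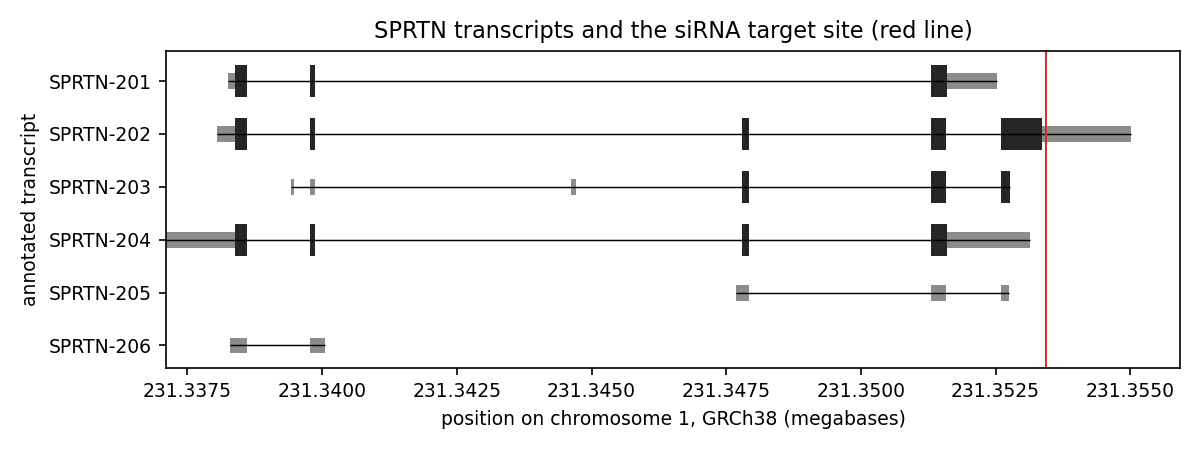
Annotated SPRTN transcripts (rows) along chromosome 1 of GRCh38 (position in megabases), with coding exon parts as tall dark bars, other exon parts as low grey bars and introns as lines. The red line marks the siRNA target at 231353422 to 231353440, which lies in the 3' UTR of 1 of the 6 transcripts.

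Among 13203 genes with a mean FPKM of at least 1, 199 were at least 2-fold higher and 104 at least 2-fold lower in the SPRTN siRNA library. The largest log2(FPKM + 1) ratio among the named genes was that of DKK4, a secreted Wnt antagonist, at 5.89 FPKM in the control and 76.8 FPKM in the SPRTN siRNA library (95% interval of the ratio 11.9- to 14.3-fold). GP2, a membrane glycoprotein of secretory granules, was 17.1-fold higher (14.3 to 20.5) from a low 1.14 FPKM. The chemokine CCL20 went from 88.8 to 477 FPKM (5.38-fold) and the aldo-keto reductase AKR1B10 from 145 to 611 FPKM (4.21-fold). The others among the 12 were MUC13, a transmembrane mucin (log2 ratio 2.71), AGR2, a disulfide isomerase of the endoplasmic reticulum (2.64), ERP27 of the same compartment (2.24), the amino acid transporter SLC6A14 (2.18), ODAM (2.12) and the histone genes HIST1H2BD (2.46), HIST1H2BK (2.13) and HIST1H2AC (2.04).

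The lowest genes began with PSMD10, the proteasome assembly factor gankyrin, at 38.5 FPKM in the control and 7.55 FPKM in the SPRTN siRNA library (5.11-fold lower, 4.63 to 5.65). The glucose transporter gene SLC2A3 went from 282 to 60.4 FPKM (4.67-fold lower) and TBCA, a tubulin folding cofactor, from 138 to 30.4 FPKM (4.52-fold lower). All 3 exceeded the difference in SPRTN. The log2 ratio was -1.92 for TRIAP1, a p53-regulated apoptosis inhibitor, -1.90 for the microtubule regulator STMN1, -1.76 for PPP1R2, -1.71 for the lysosomal membrane protein gene LAMP1 and -1.68 for THAP11. It was -1.67 for the lipid flippase subunit gene TMEM30A, -1.44 for SLBP, whose product binds the stem-loop of histone mRNAs, and -1.39 for SEL1L, a part of the degradation machinery of the endoplasmic reticulum.

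**Figure D2:**
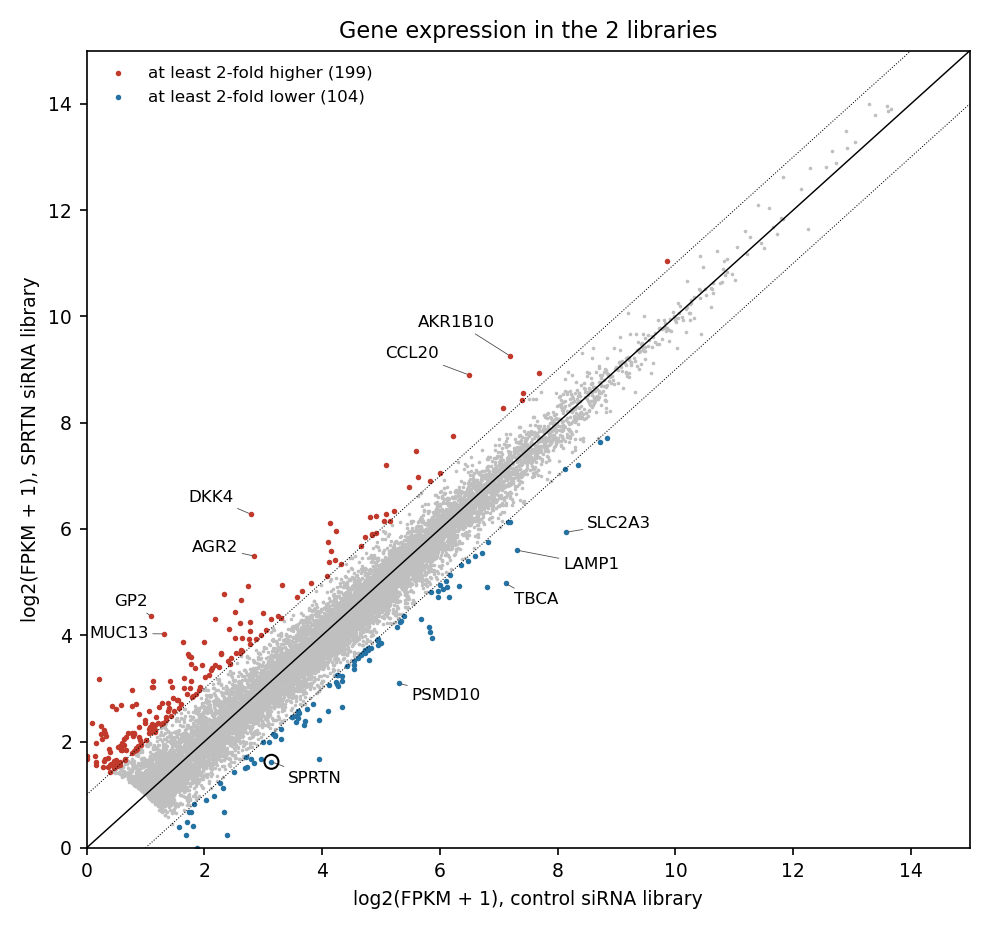
Expression of 13203 genes as log2(FPKM + 1) in the control library (horizontal axis) and the SPRTN siRNA library (vertical axis), 1 point per gene. The solid line marks equality and dotted lines a 2-fold difference; 199 genes are at least 2-fold higher (red) and 104 at least 2-fold lower (blue), and SPRTN is circled.

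Most genes differed little: the median log2 ratio was -0.05 and 84.3% of genes lay within 0.5 of 0. The counting interval excluded equality for 193 of the 199 higher and 101 of the 104 lower genes. Higher genes made up 65.7% of the 2-fold different ones, against 75.3% (222 higher, 73 lower) when the libraries were scaled by the median of ratios, 74.2% (221 and 77) when centred on the median gene, and 51.5% (86 and 81) at a mean FPKM of at least 5. A pseudocount of 0.1 gave 368 higher and 230 lower genes, and the recovered reads gave 414 and 215.

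Cell cycle transcripts were lower as a group. Of 40 G2/M genes, 39 had a log2 ratio below 0, with a median of -0.68 that lay below all 10000 random lists. Cyclin B2 (CCNB2) had a log2 ratio of -1.02, the centromeric histone gene CENPA -0.98, and topoisomerase II alpha (TOP2A) went from 278 to 138 FPKM (2.01-fold lower), while CKS2 was the exception at 0.19. The 45 genes of G1/S and DNA replication all had log2 ratios below 0, with a median of -0.53, also below all random lists. The lowest were SLBP (-1.44), the uracil-DNA glycosylase gene UNG (-1.06) and thymidylate synthase TYMS (-0.97), and cyclin E1 (CCNE1) was nearest to 0 at -0.08.

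Several DNA repair lists were lower too. The 28 measured genes of DNA-protein crosslink repair, the pathway SPRTN belongs to, had a median of -0.33, below all 10000 random lists, with 24 of the genes below 0. SPRTN is on that list, and without it the median was -0.32 (percentile 0.02). After SPRTN the lowest were the protease gene DDI2 (-0.76) and FAM111B (-0.67), and FAM111A, a replication-associated protease, was the farthest above 0 at 0.50. Homologous recombination had a median of -0.40, below all random lists, with RMI1 at -0.70, RAD54B at -0.68, BRCA1 at -0.68 and RAD52 at 0.15. The Fanconi anaemia pathway had a median of -0.28 (percentile 0.40), with FANCI at -0.85, FANCD2 at -0.66, FANCE at -0.65 and FANCL at 0.25. Mismatch repair had a median of -0.44 (percentile 0.37), with MSH6 at -0.68, EXO1 at -0.57 and MLH3 at 0.08. The topoisomerase list had a median of -0.43 (percentile 0.47), with TOP2A lowest, RMI2 at -0.72, RMI1 at -0.70 and TOP1 at 0.24. The mismatch repair and topoisomerase lists each share 1 gene with the cell cycle lists, and without it their medians were -0.31 (percentile 3.56) and -0.32 (percentile 3.47), no longer outside the random range. The crosslink repair, homologous recombination and Fanconi anaemia lists share 0 genes with the cell cycle lists. Removing shared genes therefore cannot separate their shift from that of the cell cycle lists.

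The other repair lists lay within the random range in the main analysis. Translesion synthesis had a median of -0.21 (percentile 5.44), with SHPRH at -0.72 and HLTF at -0.56. Non-homologous end joining had a median of -0.15 (percentile 17.5), with RIF1 at -1.13 and TP53BP1 at -0.51, but -0.28 (percentile 1.86) at a mean FPKM of at least 5, and base excision and single-strand break repair had -0.11 (percentile 32.4), with UNG again lowest and POLB at 0.54. Nucleotide excision repair had -0.10 (percentile 37.5), with ERCC1 at 0.57 and XPC at -0.36.

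Lower medians were found for 3 further lists, each of growth or metabolism. Spliceosome core genes had a median of -0.23 (percentile 0.17), with PRPF8 going from 260 to 130 FPKM (2.01-fold lower), SRSF3 at -0.55, HNRNPA1 at -0.46 and SF3A2 at 0.10. Ribosome biogenesis factors had a median of -0.23 (percentile 0.37), with URB2 at -0.85, UTP20 at -0.65, DDX21 at -0.47 and PPAN at 0.10. Hypoxia and glycolysis genes had a median of -0.21 (percentile 0.76), with SLC2A3 at -2.21, erythropoietin (EPO) at -0.82, LDHA at -0.76 and VEGFA at 0.28.

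The list of replication-dependent histones stood highest of the 40 tested. It had a median of 1.74 over 14 measured genes, above all 10000 random lists, and 13 of the 14 had a log2 ratio above 0. HIST1H2BD, HIST1H2BK and HIST1H2AC led, and the exception was H1F0 at -0.88, a linker histone gene that is itself expressed independently of replication. The list of nuclear and other RNAs that serve as signs of RNA quality also had a high median, 1.32 over 5 genes (above all random lists). In it the nuclear long RNAs MALAT1 (1.33) and NEAT1 (1.32) and the small nuclear RNA RN7SK (1.34, from 69 and 156 reads) were higher, and SNHG1 was at -0.06. Without a filter on low values the median of these RNAs was 0.10 (percentile 87.4; 0.73 with recovered reads) and that of the histone list 0.81, still above all random lists. The SPRTN siRNA library, though shallower, had 27505 genes above 0 FPKM, against 26565 in the control. Of the 199 genes at least 2-fold higher 139 were protein-coding, and of the 104 at least 2-fold lower 83 were. Among 345 long intergenic RNAs 13 were at least 2-fold higher and 0 lower, and among 387 processed pseudogenes 3 and 5. Whether the 2 libraries differ in RNA quality or in nuclear RNA content was not tested, and it may bear on the higher genes.

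Lists of hepatocyte genes, of bile acid and xenobiotic metabolism and of the antioxidant response had medians above those of most random lists. Hepatocyte secretory and identity genes had a median of 0.21 (percentile 99.99), with transthyretin (TTR) going from 134 to 311 FPKM (2.32-fold), VTN at 0.85 and FGA at 0.82. Of the 35 genes, 20 were above 0 and 15 below, with the transcription factor ONECUT1 at -0.46, and at a mean FPKM of at least 5 the median was 0.11 (percentile 99.4). Bile acid and xenobiotic metabolism genes had a median of 0.37, above all random lists, with 15 of 17 above 0. UGT1A1, which conjugates bilirubin, was at 1.82, CYP1A1, a target of the aryl hydrocarbon receptor, at 1.52, UGT2B7 at 0.99 and the bile acid transporter subunit SLC51A at -0.55. NRF2 targets of the antioxidant response had a median of 0.16 (percentile 99.6), with AKR1B10 at 2.07, ABCC2 at 0.59, OSGIN1 at 0.56 and ferritin heavy chain FTH1 at -0.36.

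The list of inflammatory genes and the mixed list of TGF-beta, YAP and immediate early genes also had higher medians. The list of NF-kB targets, cytokines and senescence-associated secreted factors had a median of 0.32, above all random lists (0.18, percentile 99.98, without a filter on low values), with 12 of 16 above 0. It was led by CCL20 (2.41), CXCL8 (1.41, from 0.99 FPKM in the control) and MMP3 (1.13), while NFKB1, which encodes a subunit of NF-kB, was at -1.04. TGF-beta, YAP and immediate early genes had a median of 0.28 (percentile 99.97), with 20 of 23 above 0, among them EGR1 (1.17), JUNB (1.11) and DUSP5 (0.95), and IER2 was at -0.39. All 13 mitochondrially encoded mRNAs had log2 ratios above 0, with a median of 0.25 (percentile 99.9), from MT-ATP8 at 0.02 to MT-ND2 at 0.50 and MT-ND1 at 0.80, next to MT-CYB at 0.44. Mitochondrial genes took 11.5% of the reads in the SPRTN siRNA library and 8.70% in the control.

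The p53 target list did not stand apart, with a median of 0.02 (percentile 92.6). Its members went both ways, from TRIAP1 at -1.92 to GDF15 at 1.19 (925 and 2115 FPKM). Interferon-stimulated genes, a readout of responses to foreign RNA or cytosolic DNA, had a median of -0.07 (percentile 44.8), with TRIM22 at 0.89 and IFI6 at 0.69. Apoptosis genes had -0.13 (percentile 23.4), with BCL2L11 at -0.78. Heat shock genes had -0.17 (percentile 9.11), with CRYAB at 0.62 and CHORDC1 at -0.45, and ATF4 targets had -0.07 (percentile 44.8), with CEBPB at -0.96 and DDIT4 at -0.73. Genes of endoplasmic reticulum chaperones and the unfolded protein response had 0.08 (percentile 97.0), with SEL1L at -1.39 and CREB3L3 at 1.06.

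Of the metabolic lists within the random range, cholesterol synthesis and uptake had a median of -0.15 (percentile 8.45; HMGCS1 -0.94). Fatty acid and triglyceride synthesis had -0.01 (percentile 70.6; LPIN1 -0.48, MLXIPL 0.37), and fatty acid oxidation and PPARA targets had 0.09 (percentile 95.9; CREB3L3 1.06, CPT1A 0.69). Aldehyde detoxification had -0.07 (percentile 43.4; AKR1B10 2.07, ALDH3A1 1.69), metallothioneins had -0.08 (percentile 42.6; MT1F -0.79, SLC30A10 0.74) and acute-phase proteins 0.14 (percentile 96.6; SAA4 1.19, CP -0.79). The nuclear-encoded respiratory chain had -0.10 (percentile 19.7; UQCRB -0.73, UQCRFS1 -0.44), cytosolic ribosomal proteins -0.03 (percentile 53.2; RPL5 -0.23, RPL30 -0.22) and the proteasome -0.10 (percentile 19.9; PSMB2 -0.79, PSMD2 -0.73). Extracellular matrix and adhesion genes had -0.03 (percentile 57.0; ITGA5 0.88, TGM2 -0.80), and the microRNA and siRNA machinery had 0.02 (percentile 77.9; DICER1 -0.78, AGO1 -0.64).

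Markers of other cell types were examined because they can reveal a mixed culture. Endothelial markers had a median of 0.55 over 6 genes (percentile 99.4), all at low levels: CDH5 was at 0.44 FPKM in the control and 2.74 FPKM in the SPRTN siRNA library, LYVE1 at 1.24 and 3.67, ENG at 1.40 and 3.55, and TIE1 at 1.84 and 1.07. Without a filter on low values the median was 0.22 (percentile 95.4), and over the 5 genes without a 7-base guide site it was 0.92 (percentile 99.87). Lists of fibroblast, blood and biliary markers had 4 measured genes each, too few to place, and the largest absolute log2 ratios in them were -0.47 (COL1A1), 0.12 (CD4) and 0.25 (KRT19).

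**Figure D3:**
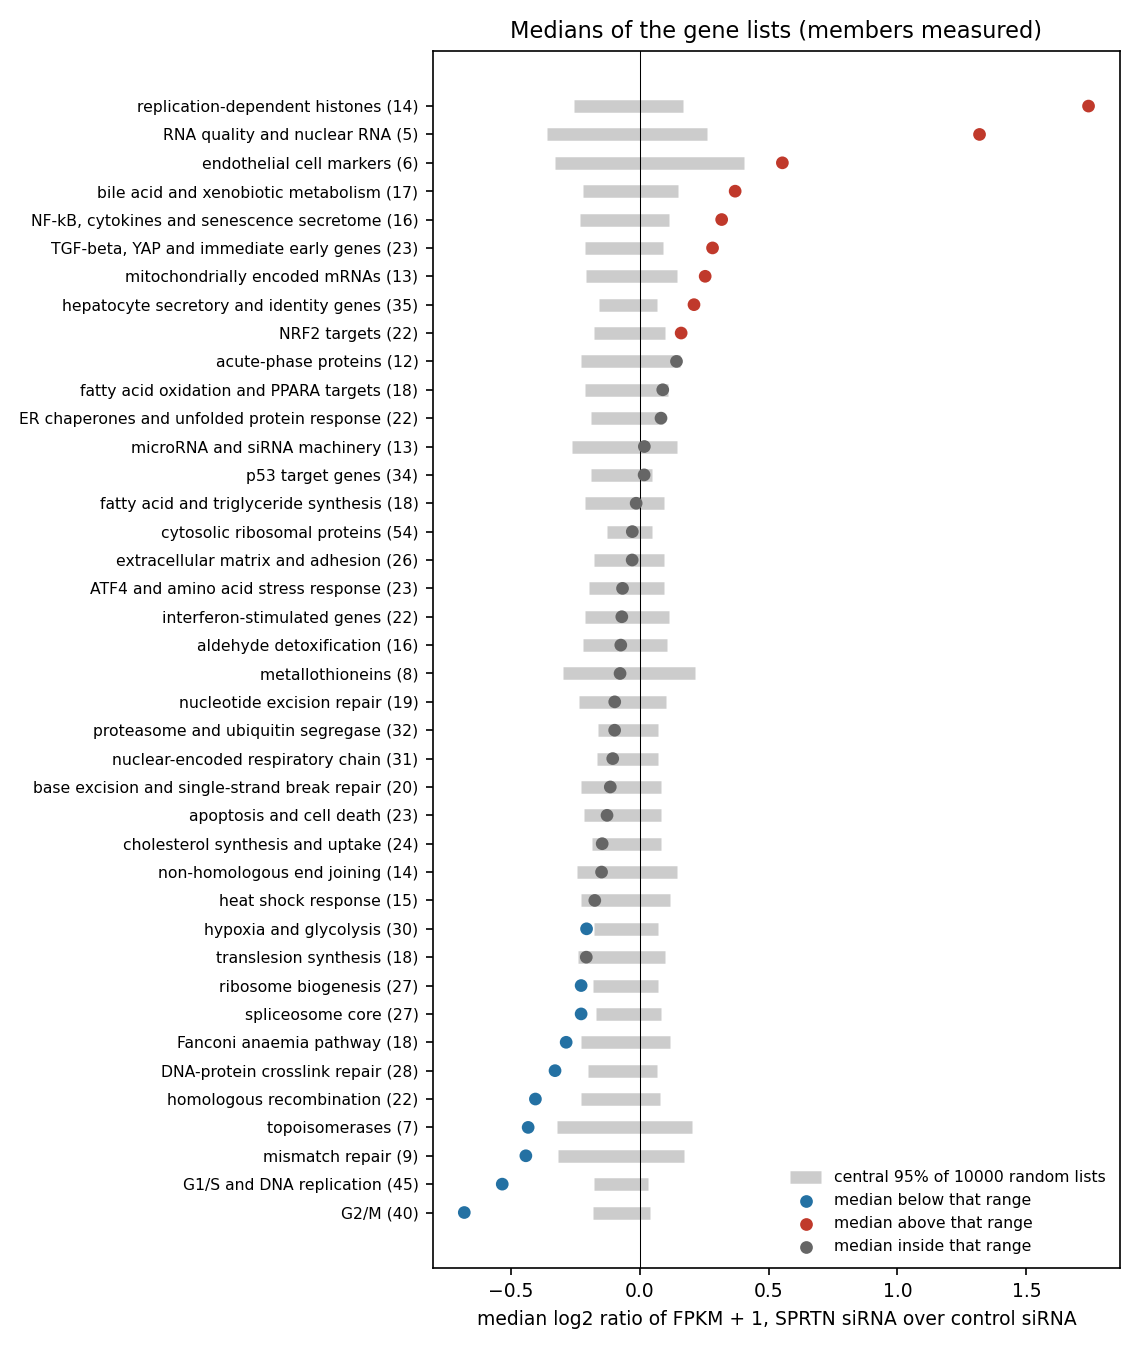
Median log2 ratio of FPKM + 1, SPRTN siRNA over control (horizontal axis), of the 40 gene lists with at least 5 measured members (rows, number of members in brackets). Grey bars span the central 95% of 10000 random lists matched on expression. Of the medians, 10 lie below their bar (blue) and 9 above (red). For lists of unrelated genes 2 of 40 would lie outside by chance, but list members are regulated together and some lists share genes.

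Sites for the siRNA's own seed were common among the lower genes. An siRNA can lower transcripts that pair with only positions 2 to 8 of its guide strand through their 3' UTR, as a microRNA does. The 384 measured genes with the 8-base guide site CTGGTTAA in a 3' UTR, SPRTN included, had a median log2 ratio of -0.33, below all 10000 lists matched on expression and 3' UTR length (central 95% of lists -0.15 to -0.08). Of these genes, 83.3% had a log2 ratio below 0, against 57.5% of genes without the site. The 780 genes with the 7-base site CTGGTTA but no 8-base site had a median of -0.20, and the 9970 genes with neither had -0.05.

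Of the protein-coding genes with a 3' UTR to search, 83 were at least 2-fold lower. Among these 83 genes, 50 held the 7-base site, SPRTN among them. That is 60.2% (exact 95% interval 48.9 to 70.8%) against 10.5% of all 11134 genes. Among the 133 genes at least 2-fold higher, 5 held the 7-base site (3.76%). PSMD10, TRIAP1, PPP1R2, LAMP1, THAP11 and SEL1L held the 8-base site, and TBCA and TMEM30A the 7-base site. SLC2A3, STMN1 and SLBP had none, and neither did any of the 11 of the 12 highest named genes that had a 3' UTR to search. Of the list members named above, RIF1 and DDI2 held the 8-base site and CENPA, UNG, LDHA, DICER1 and AGO1 the 7-base site, while TOP2A, CCNB2, TYMS, MSH6, PRPF8 and NFKB1 held none. Among genes without the 7-base site, the 10 lower lists were still under percentile 2.5, with medians of -0.66 for G2/M (38 genes), -0.53 for G1/S and DNA replication (38 genes) and -0.40 for homologous recombination (22 genes). Mismatch repair was nearest to the cut, at -0.29 over 8 genes (percentile 2.43). These lists can still hold genes with other partial guide matches, such as TGGTTAA, which were not looked up in them. For the passenger strand, the 858 genes with the 8-base site TTCCTGAA had a median of -0.12 (percentile 7.11).

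**Figure D4:**
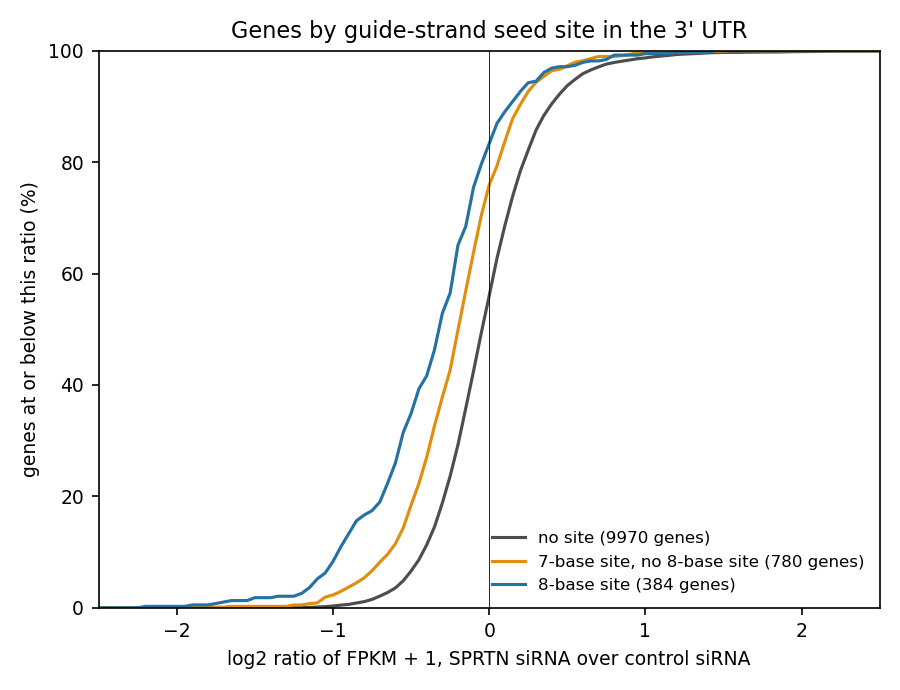
Cumulative share of genes (vertical axis, %) at or below each log2 ratio of FPKM + 1, SPRTN siRNA over control (horizontal axis), by guide-strand seed site in the 3' UTR. The curve of the 384 genes with the 8-base site (blue, median -0.33) and that of the 780 with the 7-base site alone (orange, -0.20) lie to the left of that of the 9970 genes with neither site (grey, -0.05).

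The authors' deposited table calls 3132 genes, 2302 higher and 830 lower. Of the genes called in the authors' deposited table, 611 had a mean FPKM of at least 1 (379 higher, 232 lower), and the other 2521 (80.5%) lay below. In the authors' deposited table SPRTN has a log2 fold change of -1.91 and an adjusted p of 8.75e-114, and ACTB, at a log2 fold change of -0.07, has an adjusted p of 3.63e-62. The authors' deposited table gives an adjusted p below 0.05 to 16471 of 25035 genes (65.8%), 1034 of them with an absolute log2 fold change below 0.1. These p-values compare 2 libraries and do not include the spread between cultures. For 18203 genes the adjusted p in the authors' deposited table is smaller than the p itself.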

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

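Alternatives chosen after seeing the data were the recovered reads, leaving out mitochondrial genes, genes without a guide site, repair lists without SPRTN and cell cycle members, and the 7-base passenger site; the others were planned. SPRTN was lower under every alternative run on it, with a log2 ratio of -1.86 at a pseudocount of 0.1, which shrinks a low value less, and -1.91 with recovered reads. The pseudocount of 0.1 gave 368 genes at least 2-fold higher and 230 at least 2-fold lower. The recovered reads gave 414 and 215, but that alternative differs in the measure, the prior and the tested genes (13260 of them) at once, so no single choice is set apart by it. A mean FPKM of at least 5 left 86 higher genes. Of the 19 called gene lists, 15 kept their call under all alternatives run on them and all 19 kept their sign, though not all their size. The median of the histone list was 1.74 in the main analysis and 0.81 without a filter on low values, and that of the hepatocyte list 0.21 in the main analysis and 0.11 at a mean FPKM of at least 5. Without a filter on low values the NF-kB list had 0.18, where the main analysis gave 0.32, and with recovered reads the nuclear RNAs had 0.73, where it gave 1.32. Among genes without a guide site mismatch repair had -0.29 (-0.44 in the main analysis) and the endothelial markers 0.92 (0.55 in the main analysis). Without a filter on low values the endothelial markers (0.22) and the nuclear RNAs (0.10) lost their call, as members under 1 FPKM entered. Without members of the cell cycle lists so did mismatch repair (-0.31) and the topoisomerases (-0.32), each with 1 gene fewer. The acute-phase, endoplasmic reticulum chaperone and non-homologous end joining lists gained a call under at least 1 alternative, the last with -0.28 at a mean FPKM of at least 5. The 24 genes chosen by size and SPRTN kept their sign. The seed shift was not found for the passenger strand, with medians of -0.12 for the 8-base site and -0.11 for the 7-base site (percentiles 7.11 and 37.7). TMM scaling, planned for deposited counts, was not run, since the deposited values are FPKM; the FPKM were scaled by the median of ratios as an alternative, and the recovered reads by library totals. With 1 library per group no replicate could be left out, and genes of few reads are limited by counting error.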

Other observations

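The tests of carry-over of RNA without a poly(A) tail, of abundant genes and of seed sites in the cell cycle genes, the wider set of histone genes and the scan of 7-base words were chosen after the result was seen. Of 27 measured protein-coding genes of the replication-dependent clusters, a wider set than the fixed list, 26 had a log2 ratio above 0 and 18 were at least 2-fold higher, with a median of 1.23. The 10 measured protein-coding genes with H1F, H2AF or H3F symbols, also chosen after their values were seen and not set against random lists, all had log2 ratios below 0, with a median of -0.48. Of these 10 genes, 2 held the 7-base guide site in a 3' UTR, H3F3B (-1.08) and H2AFV (-0.67). H1FX, the lowest at -1.24, held none.

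Of all 16194 words of 7 bases scanned in 3' UTRs, the guide-strand site CTGGTTA ranked second from the lowest by its score of -14.3, just after the overlapping word TGGTTAA (-14.3), which is the other part of the 8-base site. The next word, ATGGTTA, had a score of -8.48. On the side of higher genes the largest score was 4.95, for GCTCGGA, and the lowest score in 5 simulated scans with no shift was -4.38. The sequence of the control siRNA was not used here, so its own seed site could not be looked up.

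The lower protein-coding genes in the SPRTN siRNA library may be in large part seed-matched targets of the guide strand rather than a response to SPRTN loss. Genes with the 8-base site had a median of -0.33, where 95% of random lists lay between -0.15 and -0.08. Of the 83 searched protein-coding genes at least 2-fold lower, 50 held the 7-base site, the target SPRTN among them. The others of the 104 genes at least 2-fold lower were not searched. Repression by the passenger strand is argued against as the main source, with a median of -0.12 for its 8-base site and at most 36.0% of the 2-fold lower genes (upper bound of the interval) holding its 7-base site. The remaining 33 of the 83 genes had no 7-base site CTGGTTA, but other partial guide matches, such as TGGTTAA, were not looked up in them. Direct repression through such a match therefore stays open for these genes. So does an effect of SPRTN, of a seed target acting downstream or of the control siRNA, since there is 1 siRNA and 1 library per group. A second SPRTN siRNA with another seed, or rescue with an SPRTN cDNA, would separate these.

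The lower cell cycle transcripts were not accounted for by the technical explanations tested, and a difference in RNA quality was not among these. After removal of linear trends on transcript length, GC content and expression, the G2/M median was -0.56, still below all random lists. The 10 most abundant genes did take a larger share of the reads, 13.8% in the SPRTN siRNA library and 11.4% in the control. But all 13203 genes had a median of only -0.054, which argues against that larger share as the source of the G2/M shift. The 38 G2/M genes without the 7-base site CTGGTTA had a median of -0.66, so that site does not by itself give the shift. Other partial guide matches, such as TGGTTAA, were not looked up in these genes, so direct repression through them stays open. Cycling itself was not measured, and whether the lower transcripts followed from SPRTN loss, from a seed target or from a difference in cell density between the cultures cannot be read from these libraries.

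For the higher replication-dependent histone transcripts, whose mRNAs usually end in a stem-loop without a poly(A) tail, a seed site in SLBP was examined. SLBP was lower, but its 5 annotated 3' UTRs held 0 copies of the 7-base site CTGGTTA, which argues against repression through that site. Other partial guide matches, such as TGGTTAA, were not looked up in SLBP, so direct repression through them stays open. Carry-over of RNA without a tail through the oligo(dT) selection stays open. The 100 other such RNAs had a median of 0.010 against 1.74 for the histones. Of them, 10 were at least 2-fold higher and 5 at least 2-fold lower. The classes differed. The 30 snRNAs had a median of 0.23, with 6 at least 2-fold higher and 0 lower. The 69 snoRNAs had a median of -0.01, with 3 higher and 5 lower. But only 9 had at least 100 reads in the control, and RN7SK, which went with the histones at 1.34, had 69. A candidate explanation, which these data cannot test, is that less SLBP left more histone mRNA with a poly(A) tail. SLBP is also on the lower G1/S and DNA replication list, so a link with SLBP cannot be separated from the cell cycle shift. A comparison of tailed with total histone RNA, with and without SLBP restored, would test the SLBP explanation.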
